A study of Escherichia coli with 2 samples.

How the data were processed

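The series holds 2 replicate 3′ RACE libraries of Escherichia coli K-12 MG1655, described in the series design as independent, in 1 group. Per the labels' protocols, total RNA was extracted with hot phenol, treated with DNase and depleted of rRNA, a blocked 3′ adapter was ligated to RNA 3′ ends, and only then was the RNA fragmented, ligated to a 5′ adapter and reverse transcribed. Bowtie2 is named in the submitters' processing notes, without a version or a role. Per the file, the peaks came from the authors' own peak-finding script. The genome build, the read counts, the peak threshold, the treatment of reads that match several places and the way the replicates were combined are not given in the sources used here.

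The data used are 1 deposited list of peaks for both libraries together, with the interval, strand, a position within the interval and a minimum p-value for each peak, as the authors gave them; over what that p is the minimum is not stated. The position in the peak's identifier was taken as the 3′ end, and the −log10 of the authors' p as its strength, used only to describe and rank peaks. Positions are printed as deposited, on the single sequence of the list. Since no value belongs to a single replicate, leaving out a replicate or comparing replicates was not possible, and p-values concern positions on the chromosome, not the spread between cultures. No read counts enter any value, so the depth is unknown and the intervals of shares cover counting error only.

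Genes were taken from an NCBI RefSeq gene table of assembly ASM584v2 with 4290 protein genes, 107 ncRNA, 86 tRNA and 22 rRNA genes, 145 pseudogenes and 1 other RNA gene. Because the list names no build, the match of the coordinates was tested on the data. In each of 4 equal stretches of the chromosome the leaving peaks 31 to 50 nt past protein genes were counted with the table shifted by up to 3000 nt either way: with no shift there were 256, 250, 304 and 261, against at most 127, 94, 156 and 151 at any shift beyond 25 nt. Stable RNA edges gave the same answer less firmly, with 11, 21, 15 and 21 genes matched against at most 10, 6, 8 and 8 at other shifts. Shifts of a few nt are not settled by these counts, since in the third stretch a shift of −2 nt gave 310 leaving peaks. Only distances to genes are therefore given from the table, and none of its coordinates.

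The table has no strand. A peak past the right edge of a gene on the plus strand, or past the left edge on the minus strand, was called leaving, and the reverse approaching. Classes were assigned in this order: in an RNA gene or within 20 nt past it; inside a protein gene; inside a pseudogene or the tmRNA gene; within 300 nt past a gene; within 200 nt before a gene; elsewhere. Antisense ends, planned as a class, were not assigned, and the planned ranking by antisense ends was replaced by peaks on a gene's less frequent strand. Tests planned on the genome sequence (the bases before the end, hairpin energy, terminator-like ends and the RNase E cleavage context) were not run, since no genome sequence was used here.

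Chance was taken from 1000 rotations of all peaks around the chromosome by a random offset, which keep strand and spacing. A two-sided p from them cannot fall below 0.002, and the one-sided p of the codon test not below 0.001. Edges of RNA genes were matched within 3 nt. Codon positions were counted from the gene edge where the peak's strand would start. Gene lists (14 lists, 351 matched genes, of which some are in more than 1 list, with the symbols och5 and tpke11 unmatched; 1 list and 1 gene are not reported here, but count in the adjustment and in the totals) were tested with two-sided Fisher's exact tests for leaving, inside and approaching peaks against all other genes of the same kind, with leaving peaks counted up to 300 nt and approaching peaks up to 200 nt into the gap beside the gene and genes without a gap left out of both, with Benjamini-Hochberg adjustment over the lists at each place, which is the adjusted p given for a list. The density of inside peaks was set against 10000 random lists matched on gene length in 10 bins. That test was left out for small RNAs, since 54 other ncRNA genes leave little to match from. Class tests were adjusted over the classes. Strengths were compared by a permutation test with 100000 resamples, and with 2000 under each alternative.

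The windows, gene lists, kinds of test and alternatives were fixed before the data were examined, with classes, gene context and list tests that used the strand of genes. As the table has none, these were run instead as leaving, inside and approaching, a change made after the data were seen. The genes named are every leader peptide and riboswitch list member with a peak, up to 4 members of each other list with the strongest peaks, the 10 strongest peaks outside tRNA and rRNA genes, and the 10 genes with most peaks on the less frequent strand, with ties in genome order. The strand comparisons, the reading of gene direction from peaks, the density test, the position within genes, the list windows that run on into neighbouring genes, the move of positions by 1 nt and the merging of peaks within 10 nt were chosen after the data were seen. Alternatives covered the windows, the order of classes, merging of nearby peaks, the peaks at or above the median strength, uniform random positions as background, the tolerance at RNA ends and the gap between genes.

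The counting was tested on simulated data, 20019 random peaks of which 500 were planted 40 nt past edges of the 4290 protein genes and 1000 at the second codon position. The excess at 31 to 40 nt came to 481 peaks and that at the second codon position to 1024. Without planted peaks the permutation tests gave p = 0.995 for the distance and 0.657 and 0.761 for codon positions. The random peaks were placed uniformly and drawn once, while the listed peaks were concentrated in few genes. The check therefore does not show how the tests behave for peaks clustered in that way. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.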

Results

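RNA 3′ ends of Escherichia coli K-12 strain MG1655, a laboratory strain with a single circular chromosome, were mapped by 3′ RACE sequencing. In this assay an adapter is ligated to the 3′ ends of intact, rRNA-depleted RNA before the RNA is broken up, so that the ligated base marks where the RNA ended in the cell or after processing. The design held 1 group with 2 replicate libraries, so no condition was compared with another. The comparisons are therefore between the listed 3′ ends and chance positions on the same chromosome, and between classes of genes. The series title names natural aptamers that bind RNA polymerase; the aptamers themselves were not analysed here. The authors' list held 20019 peaks, 9454 on the plus strand and 10565 on the minus strand, with intervals of 1 to 27 nt and a median of 6 nt. The gene table used has no strand. Past and before a gene therefore describe the RNA that ends, which points away from the gene or towards it, and which edge is the start of the gene is known only where peaks inside it give its direction. Each peak carried 1 p-value from the authors, given below as its strength, the −log10 of that p, which ran from 4.06 to 27.3 with a median of 6.06. The list gives 1 value per peak for both libraries together, so no spread between replicates enters any value, and the read depth is unknown. Errors below are counting intervals or SDs, over rotated, shuffled or random lists for chance values and over peaks, ends or genes for means.

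The strongest 3′ ends lay shortly past protein genes and at the ends of small RNAs. Of the 10 strongest peaks outside tRNA and rRNA genes, 6 lay 44 to 60 nt past a protein gene. The strongest of all (position 3470092, minus strand, strength 27.3) lay 53 nt past tufA, which encodes elongation factor Tu. Its near-identical copy tufB had a peak 58 nt past its edge (4177186, plus, 22.7). The others were 46 nt past rpsO, a ribosomal protein gene, at a site also inside the small RNA gene sraG (3311369, minus, 23.2), and 44 nt past the outer membrane protein gene ompA (1018969, minus, 23.0). Further peaks lay 60 nt past the ribosomal protein gene rplS (2744123, minus, 22.1) and 53 nt past the cold shock gene cspA (3720314, plus, 21.5). The other 4 lay at the ends of RNA genes. Among these were ssrA, the tmRNA that frees stalled ribosomes (2755954, plus, 26.1), and ftsO, a small RNA from the end of ftsI (92657, plus, 23.9). The others were ssrS, the regulatory RNA that binds RNA polymerase (3056166, plus, 22.6), and gcvB, a small RNA that represses transporter mRNAs (2942900, plus, 22.4). Each of these 4 positions was 1 nt from the annotated edge. How reads matching both tufA and tufB were placed is not given in the sources used here.

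RNA 3′ ends clustered 31 to 50 nt past the edges of protein genes, counting also those that lay inside a neighbouring gene. A peak is called leaving when the RNA it ends points away from the gene, and approaching when it points towards it. For the gene lists below only peaks in the gap beside the gene, outside any other gene, count as leaving or approaching, which leaves genes close to a neighbour little room, and genes with no gap are left out. Between 31 and 40 nt past an edge there were 555 leaving peaks against 184 ± 13.2 (SD over 1000 rotations) by chance, a 3.02-fold excess. Between 41 and 50 nt there were 516, a 2.78-fold excess. Within 100 nt of an edge 3128 leaving peaks were listed against 1843 ± 53.7 (1.70-fold), and beyond 140 nt the counts lay near those of rotated lists. Approaching peaks had a different profile, with the highest count in the last 10 nt before the gene (421 against 184 ± 12.6, 2.29-fold) and 2488 peaks within 100 nt (1.35-fold). Both totals within 100 nt gave p = 0.002 in a two-sided permutation test by rotation, the smallest p it can give. The plot of peak counts by distance shows both profiles.

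**Figure D1:**
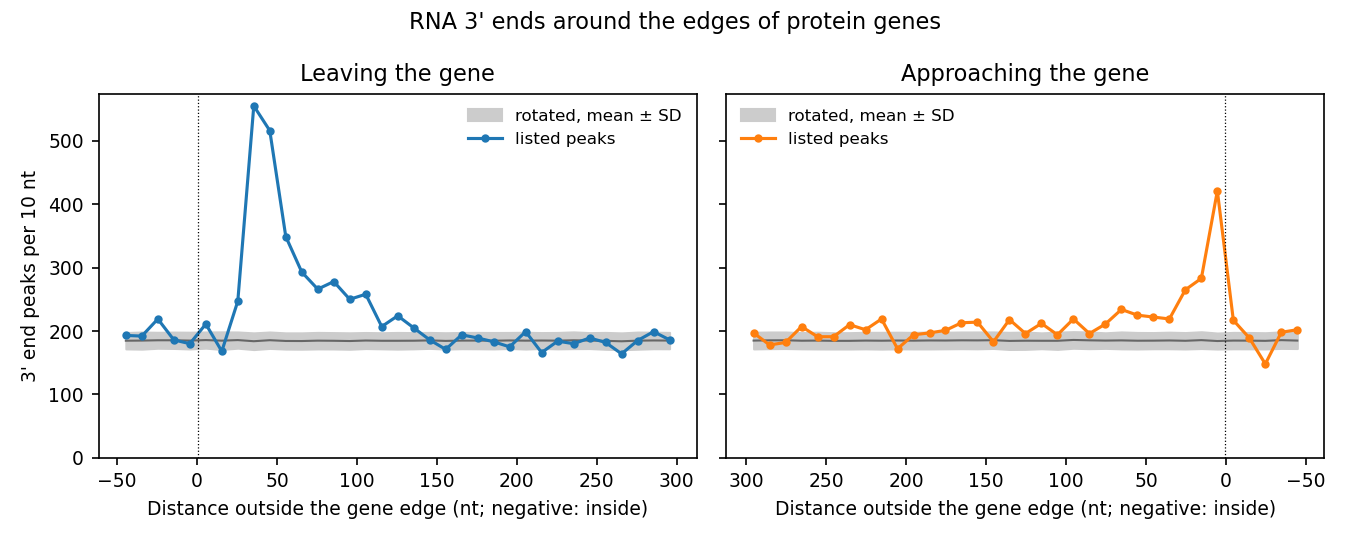
Number of 3′ end peaks per 10 nt (vertical axis) by distance from the edge of a protein gene in nt (horizontal axis, negative inside the gene), for peaks that leave the gene (left) and approach it (right); the grey line and band are the mean ± SD of 1000 rotated lists. Leaving peaks reach 555 at 31 to 40 nt, and approaching peaks reach 421 in the last 10 nt before the gene.

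By annotation, 2602 of the 20019 peaks (13.0%) lay between genes, 1.21 times the 2150 ± 82.1 of rotated lists (p = 0.002, two-sided permutation test by rotation). Peaks within 300 nt past a gene made up 12.4% of the list (95% Wilson interval 11.9 to 12.9) against 9.63 ± 0.356% by chance (adjusted p = 0.006, permutation test by rotation). Peaks inside protein genes made up 85.0% (84.5 to 85.5), which did not differ from the 85.6 ± 0.704% of rotated lists (adjusted p = 0.451, same permutation test). That share was below chance among peaks at or above the median strength (78.6%, adjusted p = 0.004, permutation test) and against uniform random positions (adjusted p = 0.0144). Peaks in or within 20 nt past tRNA, rRNA and other RNA genes made up 1.42% against 1.24 ± 0.38% (adjusted p = 0.551, permutation test). Pseudogenes together with ssrA held fewer peaks than chance, 0.804% against 2.44 ± 0.456%, as did the remaining gaps, with 0.3% before a gene and 0.0699% elsewhere (adjusted p = 0.006 each, permutation test). The deficit elsewhere did not pass with a 500 nt window (adjusted p = 0.48, permutation test) or among the stronger peaks (adjusted p = 0.102), nor did that before a gene with a 500 nt window (adjusted p = 0.128). The split between past and before a gene rests on the order in which the classes were assigned and on the window. Of the intergenic peaks 2176 (83.6%) were both, and with the leader class assigned first 1.72% lay past a gene and 10.98% before one. With a window of 100 nt for the class past a gene, 9.84% lay past a gene, 2.64% before one and 0.295% elsewhere. Each of these stayed on the same side of chance as with 300 nt.

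Among small RNAs, a peak within 3 nt of the annotated edge was found for 51 of 107 ncRNA genes (47.7%) against 3.26 ± 1.77 genes by chance. Among tRNA genes one was found for 17 of 86 (19.8%) against 2.49 ± 1.64 (p = 0.002 each, two-sided permutation test by rotation, the smallest it can give). Besides ftsO, ssrS and gcvB these included rnpB, the RNA of RNase P (3270215, minus, strength 20.0), and csrB, which sequesters the regulator CsrA (2924158, minus, 18.9). Of the 54 small RNAs in the list fixed in advance 42 had a peak inside or beside them, and dsrA, micF, rybB and sdsR were among the 12 without one. The small RNA list did not differ from other ncRNA genes, with leaving peaks at 16 of 52 members against 22.2% of others (adjusted p = 0.43, Fisher's exact test). By the same exact test this held for peaks inside 29 of 53 against 55.6% (adjusted p = 1) and approaching peaks at 12 of 52 against 8.89% (adjusted p = 0.172). The 22 rRNA genes held 0 peaks in these rRNA-depleted libraries. How reads that match several places were treated is not given, so the 0 cannot be put down to depletion alone. The same limit holds for any tRNA genes present in near-identical copies. On both strands the listed positions at ncRNA edges lay on average about 1 nt below the annotated edge. The offset was −1.30 ± 1.24 nt (SD, 27 ends) on the plus strand and −1.04 ± 1.46 nt (24 ends) on the minus strand. A peak at an annotated 3′ edge therefore tends to count as inside on the plus strand and as leaving on the minus strand. The inside and leaving counts of the small RNA list thus do not separate internal ends from ends at the edge.

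Peaks inside protein genes were concentrated in few genes. The 311 protein genes with most peaks (7.25% of 4290) held 50% of them, while 2107 genes (49.1%) held 0. The genes of the RNA polymerase subunits rpoC and rpoB led with 115 and 86 peaks. The initiation factor gene infB (78), the formate dehydrogenase gene fdoG (69) and the pyruvate transporter gene btsT (68) followed. Next came the alcohol dehydrogenase gene adhE (66), the RNase E gene rne (65) and the elongation factor gene fusA (64). These genes were chosen after their counts were seen. The counts were neither corrected for gene length nor set against chance, and long genes have more room for peaks. In each of these 8 genes all inside peaks were on 1 strand. Along the direction of the RNA, inside peaks were counted in 10 equal parts of each gene. The first part held 11.4%, the second the highest share, 12.0%, and the last 8.97%.

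Inside genes the peaks were not spread evenly over codon positions. On the plus strand 29.4% of 8007 peaks fell on the first codon position, 35.3% on the second and 35.4% on the third. On the minus strand the shares of 9029 peaks were 38.9%, 35.3% and 25.8%. The gap between the highest and lowest share was 6.01 percentage points on the plus strand and 13.1 on the minus strand, against at most 3.25 and 3.13 in any rotated list (p = 0.001 each, one-sided permutation test by rotation, the smallest it can give). The order of the codon positions depends on the 1 nt offset seen at small RNAs: with every position moved up by 1 nt, the lowest share was at the second codon position on both strands, 29.3% and 25.9%.

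The strand of peaks inside a gene matched that of the peaks leaving it. In 989 protein genes with leaving peaks on a single side within 100 nt, 96.5% of 10000 inside peaks were on the strand of the leaving peaks, against 50.2 ± 2.43% when sides were shuffled among genes (p = 0.002, two-sided permutation test, the smallest it can give). Of 1175 protein genes with at least 4 inside peaks, 997 (84.9%) had all of them on 1 strand, against 34.0 with strands drawn at random. The less frequent strand held 2.04% of 15329 peaks. The genes with most peaks on their less frequent strand were can, a carbonic anhydrase gene (6 of 19), ygfZ (5 of 12), mtgA, a glycosyltransferase gene of the cell wall (5 of 15), and dxs, for the isoprenoid precursor pathway (4 of 27). They were followed by helD, rluB and rlmD (4 of 8 each), yfcO (4 of 9), the lysyl-tRNA synthetase gene lysS (4 of 25) and the flavodoxin gene fldB (4 of 8). The gene table used has no strand, so which of these peaks are antisense was not assigned.

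Peaks past a gene were stronger than peaks inside one. Their mean strength was 8.25 ± 3.19 (SD, 2483 peaks) against 6.27 ± 1.56 (17016 peaks), with medians of 7.42 and 5.92 (difference of means 1.98; p = 1e-05, two-sided permutation test with 100000 resamples, the smallest it can give). Peaks past a gene made up 78 of the 100 strongest peaks and 549 of the 1000 strongest, and peaks inside protein genes 9 and 375. Of the intergenic peaks 83.6% were both past and before a gene, so the class past a gene rests on the order of assignment. The comparison is thus mostly one of peaks between genes with peaks inside protein genes. It was not rerun with the leader class first or with other windows. The plot of peak strength by class gives the medians and quartiles. Peaks are not independent replicates, and a strength can also rise with the abundance of the RNA, which the list does not give.

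**Figure D2:**
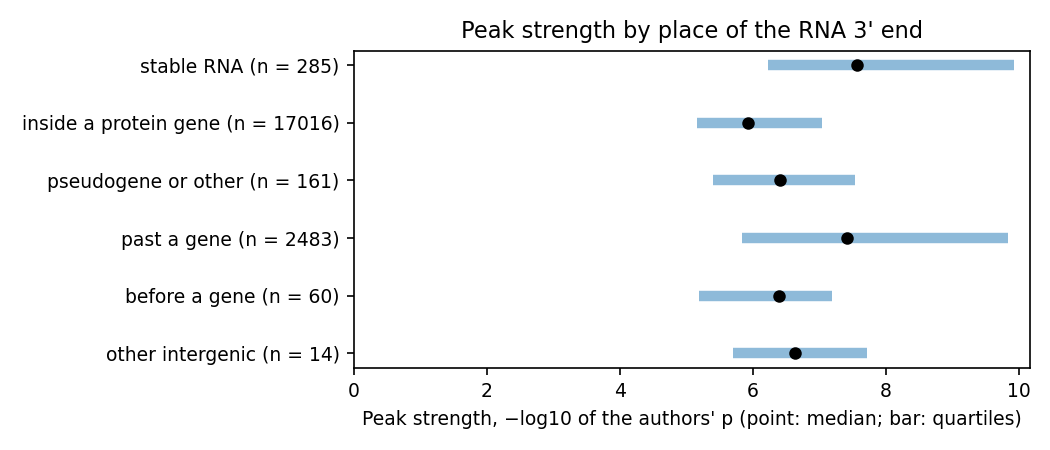
Strength of 3′ end peaks (horizontal axis, −log10 of the authors' p) by class of position (vertical axis, with the number of peaks); points are medians and bars span the quartiles. The median is 7.42 past a gene, 7.56 in RNA genes and 5.92 inside protein genes.

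Among genes whose direction could be read from at least 3 inside peaks, all on 1 strand, a peak within 300 nt past the gene was seen for 32 of 40 genes that face a gene of the opposite direction (80.0%). Genes followed at a distance of over 50 nt by a gene of the same direction had one in 201 of 219 cases (91.8%, odds ratio 2.79, adjusted p = 0.0396, Fisher's exact test). Genes followed within 50 nt had one in 67 of 335 cases (20.0%, odds ratio 0.0625, adjusted p = 1.2e-13, Fisher's exact test). The window ended at the next gene of the same direction, so close neighbours left less room for a peak, and genes without a gap counted as having none. Genes that face the opposite direction kept the full 300 nt. When the window ran on into the next gene, 96.4% of the closely followed genes had one. That next gene, however, was itself chosen for holding at least 3 peaks on the same strand. Neither share therefore tells how often RNAs end between close genes. When genes were split at a gap of 20 nt, the distant group showed no difference (82.6%, adjusted p = 0.662, Fisher's exact test). That split adds genes with gaps of over 20 and up to 50 nt, whose windows end at the next gene, to the distant group. Genes more than 50 nt from the next gene are unchanged by it.

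Leader peptide genes, short reading frames ahead of biosynthetic and other operons, often had a 3′ end in the gap past them. A leaving peak was found for 9 of 13 (69.2%) against 34.5% of other protein genes (odds ratio 4.27, adjusted p = 0.027, Fisher's exact test). With windows that run on into neighbouring genes this did not pass (84.6% against 54.5%, adjusted p = 0.0726, Fisher's exact test). A peak inside was found for 2 of 13 (15.4% against 51.0%, adjusted p = 0.0178, same exact test). With only peaks at or above the median strength the latter no longer passed (adjusted p = 0.176, exact test), and against lists of matched length no difference was found in the density inside these short genes (0.817-fold, adjusted p = 0.885, permutation test). For the branched-chain amino acid operons the strongest lay 54 nt past ilvL (3950474, plus, strength 17.6) and 60 nt past ivbL (3852830, minus, 15.9). Ahead of the histidine, leucine and phenylalanine genes they lay 85 nt past hisL (2090131, plus, 12.2) and 38 nt past leuL (83584, minus, 6.84), and then 74 nt past pheL (2737720, plus, 7.24) and 244 nt past pheM (1798982, minus, 6.93). Further leaving peaks lay 193 nt past tnaC of the tryptophanase operon (3888702, plus, 12.3) and 48 nt past mgtL (4467532, plus, 10.6). The members thrL, trpL, pyrL and idlP had 0 peaks inside or beside them. Approaching peaks, at 4 of 13 against 29.5% of others, did not differ (adjusted p = 1, Fisher's exact test).

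All 10 genes controlled by riboswitches or similar leader RNAs had an approaching peak within 200 nt, against 29.3% of other protein genes (adjusted p = 6.7e-05, Fisher's exact test). In the thiamine genes the strongest of these lay 40 nt before thiM (2185341, minus, strength 5.04), 48 nt before thiC (4196147, minus, 8.77) and 34 nt before thiB (75514, minus, 7.54). Others lay 74 nt before btuB, the cobalamin receptor gene (4163565, plus, 9.38), and 96 nt before ribB of riboflavin synthesis (3184562, minus, 8.65). Peaks also lay 86 nt before lysC, an aspartokinase gene (4233319, minus, 6.51), 15 nt before moaA of molybdopterin synthesis (817029, plus, 9.19) and 45 nt before alx (3239590, minus, 6.01). At the manganese exporter gene mntP the only approaching peak (1905682, plus, 5.26, 6 nt) was on the opposite strand from its inside peak. At the magnesium transporter gene mgtA the strongest (4470488, minus, 13.2, 167 nt) was opposite to the strongest inside peak, while 5 of its 9 approaching peaks were on the plus strand. By the rule of at least 3 inside peaks, all on 1 strand, a direction was read only for btuB, ribB, lysC and moaA. None was read for thiM, thiC, thiB, mntP and mgtA, or for alx, which had no inside peak. The count of 10 therefore includes peaks that need not lie before the start of the gene. Peaks inside were found in 9 of 10 (adjusted p = 0.0274, Fisher's exact test) and leaving peaks at 3 of 10 against 34.6% (adjusted p = 1). Their mean of 6.18 inside peaks per kb did not differ from gene lists of matched length (1.45-fold, adjusted p = 0.454, permutation test).

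Genes of ribosomal proteins, ATP synthase, the transcription machinery and RNA processing were dense in 3′ ends. All 54 ribosomal protein genes had inside peaks, with 31.5 ± 9.24 per kb (SD over genes), 6.65 times the mean of random lists matched on gene length (adjusted p = 4.3e-04, two-sided permutation test with 10000 lists). This adjusted p comes from the smallest p that this permutation test can give, 0.0002. The same holds wherever 4.3e-04 is given below, so these p-values do not rank the lists. Leaving peaks were found at 34 of 53 (64.2% against 34.2%, adjusted p = 9.6e-05, Fisher's exact test), and at all 54 when windows run on into neighbouring genes (against 54.0%). Examples are rplS (above), rpmA (57 nt past, 3332805, minus, strength 20.4), rplL (71 nt past, 4180996, plus, 19.4) and rplI (50 nt past, 4426607, plus, 19.2). The 9 ATP synthase genes had 29.2 ± 6.64 per kb (5.73-fold, adjusted p = 4.3e-04, permutation test). The strongest peaks of these genes all lay on the minus strand between 3915501 and 3922321, so the genes may share RNAs. Leaving peaks, at 6 of 9, did not pass (66.7% against 34.5%, adjusted p = 0.101, Fisher's exact test). They did so with windows that run on into neighbouring genes (9 of 9, adjusted p = 0.0102, same exact test). Such windows also count peaks inside the neighbouring gene. For the ribosomal protein and ATP synthase lists their result is therefore not separate from the density inside genes. The strongest peaks of the ATP synthase genes lay 52 nt past atpC (3915501, minus, 18.0), between atpA and atpG (36 nt past atpA, 3918280, minus, 15.1) and inside atpF (3920787, minus, 12.7). Genes of RNA polymerase, sigma factors and elongation factors had 17.7 ± 10.6 per kb (3.63-fold, adjusted p = 4.3e-04, permutation test). Leaving peaks were found at 16 of 21 of them (adjusted p = 3.3e-04, Fisher's exact test). Examples were nusB (51 nt past, 435607, plus, 19.2), rpoC (47 nt, 4189620, plus, 14.9) and rpoH (50 nt, 3599879, minus, 14.7). The strongest peak of rpoB was 185 nt before the gene (4181060, plus, 15.3). RNase and RNA processing genes had 15.4 ± 11.5 per kb (3.37-fold, adjusted p = 4.3e-04, permutation test) and leaving peaks at 13 of 18 (adjusted p = 0.00343, Fisher's exact test). These included hfq (53 nt, 4400649, plus, 15.8), pnp (39 nt, 3308994, minus, 15.2) and csrA (39 nt, 2818922, minus, 13.4). The strongest peak of the list was inside rnpA (3884540, plus, 16.7).

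Outer membrane protein genes had 16.6 ± 10.7 inside peaks per kb (3.76-fold over lists of matched length, adjusted p = 4.3e-04, permutation test) and leaving peaks at 15 of 19 (adjusted p = 3.3e-04, Fisher's exact test). Besides ompA these lay 43 nt past ompC (2311603, minus, strength 20.2), 38 nt past tsx (431091, minus, 17.0) and 56 nt past ompF (985838, minus, 16.6), all channel genes. Cold and heat shock genes had 11.6 ± 10.2 per kb (2.46-fold, adjusted p = 0.00223, permutation test) and leaving peaks at 17 of 22 (adjusted p = 2.4e-04, Fisher's exact test). The strongest after cspA were at cspE (46 nt, 657547, plus, 19.8), the chaperone gene groL (58 nt, 4372729, plus, 19.3) and grpE (54 nt, 2750061, minus, 19.4). Genes of the TCA cycle had inside peaks in 13 of 16 members (81.2% against 50.8%, adjusted p = 0.0274, Fisher's exact test). Their density (1.78-fold, adjusted p = 0.139, permutation test) and leaving peaks (7 of 14, adjusted p = 0.335, Fisher's exact test) did not pass. Examples are acnB (65 nt past, 134277, plus, 17.7), the site between sdhB and sucA (125 nt past sdhB, 758530, plus, 17.3) and icd (48 nt, 1196421, plus, 14.5).

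Of the protein gene lists described here, flagellar and chemotaxis genes had the lowest share of members with a leaving peak and the lowest density of peaks inside. Leaving peaks were found for 2 of 44 members (4.55% against 35.0%, odds ratio 0.0886, adjusted p = 4.5e-05, Fisher's exact test) and for 9 of 47 when windows run on into neighbouring genes (19.1% against 55.0%, adjusted p = 6.1e-06, Fisher's exact test). Inside peaks were found for 12 of 47 (25.5% against 51.2%, adjusted p = 0.00205, same exact test). The density inside was 0.854 ± 1.94 per kb, 0.175 times that of lists of matched length (adjusted p = 4.3e-04, permutation test). The strongest were between flgG and flgH (31 nt past flgG, 1135542, plus, strength 11.3), inside flgB (1131332, plus, 8.01) and 45 nt past cheZ (1966348, minus, 7.56). Toxin-antitoxin genes had inside peaks in 10 of 40 members (25.0% against 51.1%, adjusted p = 0.00281, Fisher's exact test). For these short genes the density did not differ from lists of matched length (0.509-fold, adjusted p = 0.082, permutation test), but did so among peaks at or above the median strength (0.212-fold, adjusted p = 0.00812). Their strongest peaks approached chpB at 25 nt (4449067, minus, 16.2), left shoB at 59 nt (2700058, minus, 11.5) and approached higB at 177 nt (3234632, minus, 11.2) and chpS at 178 nt (4448269, plus, 10.7). None of these 4 genes had an inside peak, so whether the peaks lie at their start or their end was not read. Stationary phase and stress genes did not pass in leaving peaks over the whole list (14 of 25, adjusted p = 0.0517, Fisher's exact test; 0.0236 among peaks at or above the median strength and up to 0.455 under the other alternatives) or density (0.978-fold, adjusted p = 0.996, permutation test). Strong single peaks lay 13 nt from rmf, approaching an edge that was not read as its start or end (1015895, minus, 18.5), 69 nt past dps (848339, minus, 18.3), 81 nt past sodA (4101511, plus, 18.3) and 154 nt past sodB (1736113, plus, 16.1). In all, 23 of the 42 list tests passed an adjusted p of 0.05. The exact tests and the density tests treat each gene as independent, while list members that lie close together on 1 strand may share RNAs. The p-values of such lists may therefore be too small. Abundant RNAs can yield more detectable ends, and expression was not corrected for. A high or low count therefore does not separate how often RNAs end from how abundant they are.

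**Figure D3:**
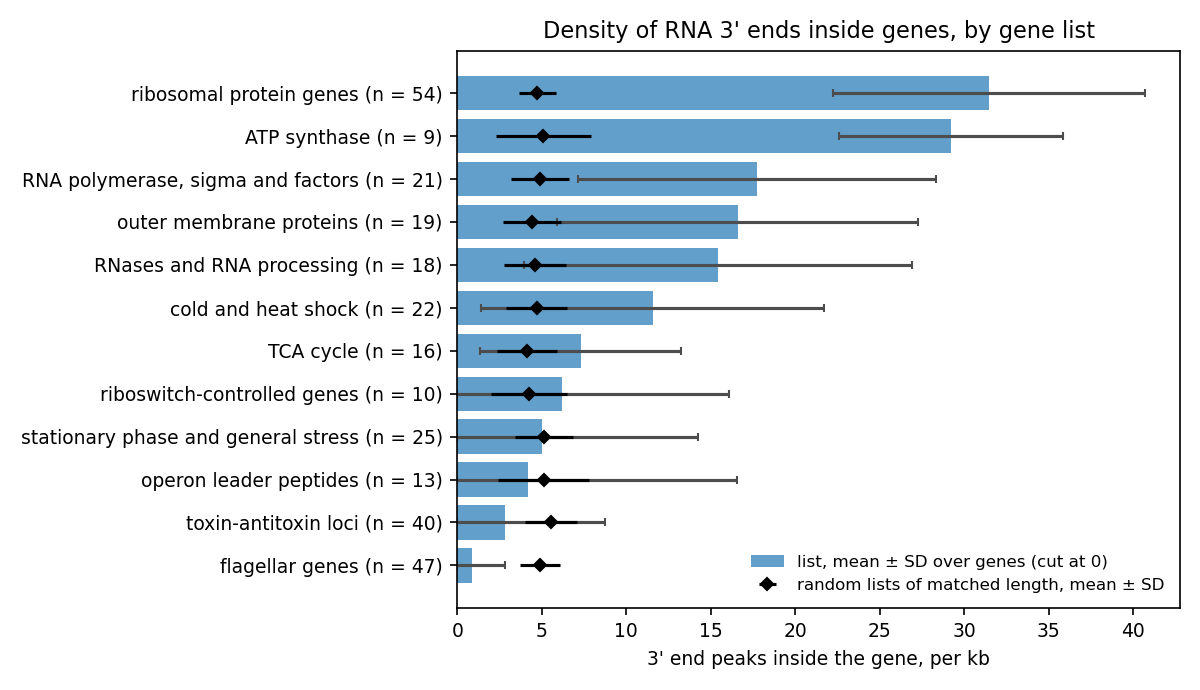
Mean number of 3′ end peaks inside the gene per kb (horizontal axis) for 12 lists of protein genes (vertical axis, with the number of genes); bars are means with the SD over genes, and diamonds the mean ± SD of random lists matched on gene length. Ribosomal protein genes reach 31.5 and flagellar genes 0.854.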

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

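The merging within 10 nt, the 1 nt move, the removal of the 100 genes with most peaks, the windows run past the next gene, the windows of the strand comparison and, outside the classes and distances, the restriction to stronger peaks were chosen after the results were seen. Over 332 alternative values under 16 settings, most kept their direction and side of the threshold: the excess of leaving peaks within 100 nt ranged from 1.70 to 2.28-fold, the number of list tests passed from 23 to 25, and the strength difference from 1.97 to 1.99. With a 500 nt window the deficits before a gene (0.0899%) and elsewhere between genes (0.025%) no longer passed, since the wider class took their peaks. With the leader class assigned first, peaks past a gene fell to 1.72% and peaks before one came to 10.98%, both on the other side of chance, because most intergenic peaks meet both definitions. The strength comparison was not rerun with that order or with other windows, so its narrow range does not cover them. With only peaks at or above the median strength, the share inside protein genes was 78.6% and below chance, and the deficit elsewhere between genes (0.0998%) no longer passed. The share inside of 85.0% also passed as below chance against uniform random positions. In these cases the cause was not tested. In the gene context, distant neighbours no longer differed at a gap of 20 nt (82.6%), the cause of which was not tested, and closely followed genes came to 96.4%, above genes with an opposite neighbour, once the window ran past the next gene, which lengthens it. Among single lists 7 values gained and 4 lost their pass, with the stronger peaks or with windows run on into neighbouring genes. Under the latter the leaving peaks of leader peptide genes (84.6%) no longer passed and those of flagellar genes (19.1%) still did. Merging within 5 nt moved 0 peaks, since peaks of a strand are at least 6 nt apart, and leaving out tRNA and rRNA genes moves nothing in the strength comparison. Neither says anything about stability. The same holds for the inside and approaching list tests under the 100 nt window for leaving peaks, and for the inside list tests under windows run on. These settings cannot change such values, which are nevertheless counted among the 332. Alternatives on the genome sequence and on single replicates were not run. No paired analysis was possible because there is 1 group. The unknown depth limits every count, since ends of scarce RNAs can go unlisted.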

Other observations

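The test of the strongest peaks inside genes and the tests on the 1 nt offset and on interval widths were chosen after the results were seen. So were the counts at the first base of genes and over 40 nt before their edges on either strand. The ratios of peaks before and inside the first edge were set out beforehand, but without the 1 nt move of positions used in them. Many of the strongest peaks that fall inside a protein gene lay shortly past the edge of its neighbour. Of the 100 strongest inside peaks 41 were within 100 nt past another protein gene, against 6.56% of the other 16916 (odds ratio 9.91, p = 2.2e-22, Fisher's exact test). The strongest lay in yjaH, 51 nt past hupA, the gene of a histone-like DNA-binding protein (4200604, plus, strength 21.1), followed by a peak in fdhE, 74 nt past the formate dehydrogenase gene fdoI (4081151, minus, 18.2), and by one in yifB, 26 nt past maoP (3948450, plus, 17.2). Others with a clear neighbour were in rnpA, 64 nt past rpmH (3884540, plus, 16.7), and in yhfK, 41 nt past the regulator gene crp (3486793, plus, 15.1). A counterexample is the peak in ptsI, 322 nt past ptsH (2534343, plus, 17.1), both of the sugar phosphotransferase system.

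In the operon of ribosomal and RNA polymerase genes 11 peaks lay within 300 nt past rplL, the strongest 71 nt past it (strength 19.4), and the strongest of those approaching rpoB lay 185 nt before it (15.3). Within 200 nt before rplJ there were 7 approaching peaks, the strongest 182 nt before the gene (4179814, plus). Ahead of oppA, the gene of the oligopeptide-binding protein, 6 of the strongest 10 peaks that lay far from any gene edge were found between 232 and 319 nt before the gene (strengths 6.71 to 9.97), past the insertion sequence gene insH21. Among genes of at least 300 nt the highest densities of inside peaks were at rplL (43.7 per kb), rpsE (43.7), atpH (41.2) and rpsH (40.7). The longest protein genes without an inside peak were yeeJ, ypjA, rhsD, rhsB, rhsA, entF and narZ. These genes were named after their values were seen.

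The listed positions at ncRNA edges lay below the annotated edge on both strands, in 22 of 27 ends on the plus strand and 18 of 24 on the minus strand. Ends exactly at the edge were left out of the sign test. On the plus strand it set 22 below against 3 above (p = 1.6e-04, two-sided exact sign test). On the minus strand it set 18 below against 4 above (p = 0.00434, same exact test). A candidate explanation is that positions were counted from 0, since trimming of the RNA would mirror the offset on the minus strand, where its mean was −1.04 nt. With positions moved up by 1 nt, the summed difference between the codon shares of the strands dropped from 19.1 to 6.92 percentage points, which also goes with counting from 0. At tRNA edges, however, 5 of 10 plus-strand ends lay below and 5 above (mean −0.1 ± 1.45 nt, SD), while 6 of 7 minus-strand ends lay below (−1.29 ± 0.951 nt), so the offset was not seen at plus-strand tRNA ends. No biological explanation was tested.

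Intervals were wider on the plus strand, with a median of 6 nt against 5 nt and 0.339% against 30.7% under 3 nt. The position of the peak lay 2 nt before the right end in 39.6% of plus-strand intervals and at the right end in 33.4% of minus-strand ones. The largest difference between the cumulative widths dropped from 0.303 to 0.0969 once 2 nt were taken off the right end of plus-strand intervals, so 2 nt added in writing the list may account for most of it. Positions, which all counts use, are not touched by this, and no biological explanation was tested.

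The counts in this paragraph use positions moved up by 1 nt, which can carry a peak across an edge. Approaching peaks piled up directly before protein genes, counted in 1166 genes whose direction was read from their inside peaks. On the gene's own strand 144 peaks lay in the 10 nt before its first base and 90 in the 10 nt from the first base on. The ratio was 1.60 (95% exact interval 1.22 to 2.11). From 2 nt before to 1 nt after the first base lay 100 peaks, in a window set where the counts were highest. This was 2.07 times as many per nt as 11 to 40 nt away (1.66 to 2.56). Ends of neighbours that run the other way lie on the other strand and cannot make up an own-strand excess, which over the whole 10 nt was small, 1.25 times as many per nt as the 345 peaks 11 to 40 nt before (1.02 to 1.53), and the interval of the ratio reaches both above and below the 1.5 set as its bound. On the other strand, where such ends could add peaks, 42 lay in the 10 nt outside the last edge of these genes, pointing towards it, by the same measure a stronger excess of 2.93 times over the 43 peaks 11 to 40 nt outside it (1.87 to 4.59). The stop codon of a close upstream gene could also place ends there: in 519 genes with no gene within 100 nt before them the ratio was 1.81 (0.952 to 3.57) and the fold at the first base 1.75 (1.03 to 2.82), too few peaks to decide. Choosing genes by their inside peaks raises the count after the first base, and no biological explanation was tested.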
